A study of Mus musculus with 17 samples.

How the data were processed

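Total RNA from mouse uteri was labelled with biotin and hybridised to Illumina MouseWG-6 v2 bead arrays, per the labels' protocols. The 17 arrays fall into 8 groups set by Egr1 knockout status (KO or WT) and by the time after estradiol (E2), which was 0, 3, 6 or 24 h. Each group has 2 arrays except WT 3 h, which has 3, and the group and replicate number of every array were taken from its labels. The E2 dose, the age of the mice, any ovariectomy and any vehicle treatment are not given in the sources used here. The scanner values were read with BeadStudio (version not stated), per the submitters' processing notes, and the series text names expression values and detection calls as derived from these. The detection calls and the scanner values were not used here. The deposited values are log2 values that the authors had quantile normalized between arrays, read from the table itself: all 17 columns share the same quantiles, with a median of 8.20 and a 75th percentile of 8.87, and the values run from 7.39 to 15.94. Background correction, log offset and normalization software are not given in the sources used here, so a floor set by them can compress the differences of dim probes. No depth applies to these arrays, and their number limits the precision.

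The table holds 45281 probes. The platform annotation listed 34903 of them, 34885 with 1 gene symbol and 18 with several, and left 10378 unlisted. Of the listed probes 34807 matched the RefSeq gene table of assembly GRCm38 through their Entrez number, and the match changed 0 symbols. Only probes with 1 symbol were used, which gave 19057 symbols. A probe was kept if it lay above the array median on at least 2 of the 17 arrays, and the probe with the highest mean over all arrays stood for its gene, which left 14737 genes. The array has no stated genome build, and no coordinates are given.

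A linear model with a mean for each of the 8 groups was fitted to the 17 arrays with limma 3.58.1 in R 4.3.3, followed by empirical Bayes moderation without an intensity trend. The residual degrees of freedom were 9 and the prior degrees of freedom 4.56. Every adjusted p-value comes from limma, with the Benjamini-Hochberg adjustment over the 14737 genes within a comparison and a threshold of 0.05. All tests were two-sided. The comparisons were each time against 0 h within a genotype, KO against WT at each time, KO against WT averaged over the 4 times with equal weights, and the genotype by time interaction, which is the KO change minus the WT change, tested for each time and jointly with a moderated F-test. The replicate number in the labels was not used as a block, since no label ties it to a litter, a day or an animal. Nothing in the labels says that the samples of a group came from separate animals, so the p-values measure only the spread between these samples, which may be technical.

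The gene lists, the tests and the rule for naming genes were fixed before the data were examined. The 16 pathway lists were immediate-early genes, EGR1 feedback and reported EGR1 target genes, early estrogen-response genes, late estrogen-response secretory genes, DNA replication and G1/S, mitosis and G2/M, progesterone-response genes, unfolded protein response, ribosome biogenesis, cholesterol synthesis, glycolysis, interferon-stimulated genes, chemokines and cytokines, Wnt signalling, steroid and nuclear receptors, and extracellular matrix. The 11 marker lists were epithelial, smooth muscle, stromal fibroblast, endothelial, macrophage, granulocyte, lymphocyte, adipocyte, mesothelial, erythroid, and ovary and oviduct. Whole uterus holds several of these cell types, and 15 of the 433 measured members stand in more than 1 list, so those lists' tests are not independent. They are Lum and Dcn (matrix, fibroblast), Fn1 (EGR1 targets, matrix), Mad2l1 (EGR1 targets, mitosis), Vegfa (EGR1 targets, early response), Wnt4 and Wnt5a (early response, Wnt), Slc2a1 (early response, glycolysis), Fst (early and progesterone response), Pgr (these 2 and receptors), Nr2f2 (progesterone response, receptors), Hand2 and Hoxa11 (progesterone response, fibroblast), Rspo1 (Wnt, mesothelial) and Ovgp1 (late response, oviduct). The 25 lists with at least 5 measured members were tested with limma's camera at a preset correlation of 0.01 between genes, adjusted over lists. Camera compares a list with the other genes. The same test was run with the correlation estimated from the data, and fry tested whether a list's genes moved, on balance, 1 way. Members past the gene test were counted after adjustment over all genes and also adjusted over the list alone.

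The genes named for a comparison were the 10 with the largest rise and the 10 with the largest fall among those past the threshold whose groups did not overlap on any array. For the interaction they were the 10 with the smallest F-test p-value, and the 5 highest and 5 lowest at each time. Up to 4 members of each list with the largest change in a comparison were named too, and gene models with clone names were left out. Other named genes are said to have been chosen after their values were seen. Of the 250 named pairs of a gene and a comparison, 116 had more than 1 kept probe, 12 had a probe of the opposite sign, and 48 more had a probe that changed by less than 25% of the value given. Dim or misplaced probes and transcript forms were not told apart.

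The alternatives were a quantile rescaling, a shift to a common 75th percentile, 2 other filters on dim probes, an intensity trend with a robust prior, the mean of all probes of a gene, a fit on the compared groups alone, the replicate number or title letter as a block, and leaving out each array in turn. Cyclic loess, the first WT 0 h array left out, crossed replicate numbers, and the list tests under other filters and without each array were added after seeing the data. The fits were tested on simulated data for the same 14737 genes. For KO against WT at 24 h, 16% of the genes changed by 0.25 log2 were recovered, 94% at 0.5, 96% at 1 and 98% at 2. For the average over times 90% were recovered at 0.25, and for the joint interaction test 38% at 0.5 and 96% at 1. False calls made up 3.80% of the calls in the first of these, 3.98% in the second and 6.40% in the third. In a further simulation with 200 unchanged lists, camera called 0 of them and called the shifted one. The simulated genes varied independently of each other, so this does not test camera on lists of correlated genes. Each simulated gene had the same spread in all groups, while the real groups differed (median SD from 0.0384 in WT 24 h to 0.0780 in WT 0 h). The false-call rates therefore do not cover unequal spread, and KO against WT at 0 h and at 6 h was not simulated.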

Results

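The study measured gene expression in whole uteri of Egr1 knockout (KO) and wild-type (WT) mice before estradiol (E2) and 3, 6 and 24 h later. The labels name a genotype and a time for each of the 17 arrays, 9 of WT and 8 of KO uteri. Below, KO and WT stand for arrays labelled KO and arrays labelled WT. Values are log2 and already normalized between arrays, so every change is relative to the other genes of the same array. A gene's value is that of its brightest probe. For 48 of the 250 pairs of a gene and a comparison named by the rule another probe of the same sign changed by less than 25% of the value given. This concerns Klk1b5, Klk1b26, Col8a2, Sesn1, Ypel3, Bace2, Pamr1, Lpl (-0.06 against -2.99 in WT at 24 h), Galnt15, Plat, P4ha2, Tsc22d3, Tk1 (0.05 against 2.80 in KO at 24 h), Amy2a5, Wfikkn2 (0.14 against 1.88 in KO against WT at 0 h), Bex4 (0.07 against 1.43), Rasgrf1 (-0.03 against -1.73), Slc7a11, P2ry14, Ltf (0.05 against 1.67 in KO against WT at 3 h), Arhgap35, Ccnd3, Slc6a2, St6gal1, Ppp1r1b, Sned1 and Hif3a. The correlation across all probes was 0.990 to 0.997 between arrays of a group and 0.982 to 0.994 between arrays of the same time and the other genotype. No 2 arrays held identical values. With 2 arrays in most groups the number of arrays limits the precision.

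Some arrays stood apart from the other array of their group in the mean of a gene list, given here relative to all 17 arrays. In the first WT 0 h array the DNA replication list lay at 0.30 and the mitosis list at 0.33, against -0.33 and -0.27 in the second. Its mean correlation across all probes with the 24 h arrays was 0.974, against 0.950 to 0.952 for the other 0 h arrays. The macrophage markers lay at 0.93 and the granulocyte markers at 0.86 in the second KO 0 h array, against 0.17 and -0.04 in the first. The second KO 3 h array had higher adipocyte markers (0.33 against -0.67) and interferon-stimulated genes (0.51 against -0.29) than the first, and the second KO 6 h array had higher adipocyte markers (0.45 against -0.65). Where a list call was lost or its median shrank without 1 array, the value without it is given for the lists named.

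Egr1 is the disrupted gene, and 1 probe, ILMN_2662926, measured it. Where the probe lies relative to the disrupted part of the gene is not given in the sources used here, so its level does not check the labels. It was not lower in the KO arrays. At 0 h its mean was 13.55 ± 0.11 (SD, n = 2) in KO and 12.37 ± 0.19 (SD, n = 2) in WT, and KO exceeded WT by 1.18 (limma, adjusted p = 3.02e-03; 0.0649 in a fit of these 2 groups alone). In WT Egr1 rose by 2.42 at 3 h (adjusted p = 6.82e-08) to 14.79 ± 0.20 (SD, n = 3), was still 1.54 higher at 6 h (1.11e-05), and lay below its start at 24 h, by -0.63 (1.36e-02). That fall did not pass the test without the second WT 0 h array (-0.50) or without the first WT 24 h array (-0.29). In KO the signal rose by 1.09 at 3 h (2.65e-04) and by 1.09 at 6 h (1.91e-04), and its change at 24 h of -0.16 did not pass the test (5.49e-01; interaction 0.47, 3.13e-01). KO and WT did not differ at 3 h (-0.15, 6.95e-01) or at 6 h (0.73, 9.24e-02) by the test, and KO was 1.65 higher at 24 h (1.47e-04). The rise at 3 h was smaller in KO than in WT, with an interaction of -1.33 (2.41e-02). Because this signal runs against a loss of the transcript, each direction between KO and WT below is a direction between the labels.

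**Figure D1:**
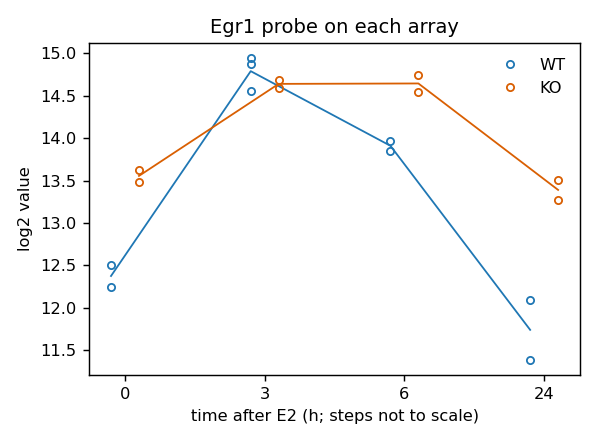
Log2 signal of the Egr1 probe on each array (points) and its group mean (lines) in WT and KO, against hours since E2. The KO arrays lie above the WT arrays at 0 h (means of 13.55 and 12.37) and at 24 h (13.39 and 11.74).

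The first question is how the WT uterus responded to E2 in the first hours. At 3 h 6880 of 14737 genes passed the test, 3272 higher and 3608 lower, and 777 of them changed at least 2-fold. At 6 h the count was 6482, with 3228 higher, 3254 lower and 881 changed at least 2-fold. The groups did not overlap for 60.0% of all genes at 3 h, where chance gives 20%, and for 68.0% at 6 h, where chance gives 33.3%.

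The largest rises at 3 h in WT were those of Phf21b (4.64 ± 0.17 SE, adjusted p = 6.83e-10), Chac1 (4.08 ± 0.56, 3.33e-05), the matrix protease gene Adamts4 (4.01 ± 0.15, 7.12e-10), the kallikrein gene Klk1 (3.98), the transporter gene Slc6a13 (3.85), Socs3 (3.74), Col8a2 (3.61), Tmem200a (3.58) and Fos (3.49). Klk1, Klk1b5 (3.58 at 3 h), Klk1b26 (3.54 at 6 h) and Klk1b27 (2.85 at 6 h) are near-identical kallikrein genes whose probes can share targets, so which of them rose is uncertain. Of 25 immediate-early genes 21 rose and 2 fell at 3 h (22 and 2 adjusted over the list alone), with a median of 0.98 (camera adjusted p = 2.60e-09), led by Socs3, Fos, Egr3 (2.60) and Gadd45g (2.58). At 6 h 15 of them rose and the median was 0.47 (3.66e-04), or 0.30 without the first WT 0 h array (7.28e-03). Of 22 early estrogen-response genes 15 rose at 3 h (16 adjusted over the list alone) and 18 at 6 h, among them Ramp3 (3.07 at 3 h), Greb1 (2.80), Wnt4 (2.75), Errfi1 (2.49) and, at 6 h, Cdkn1a (2.11) and Igf1 (1.65). The list of reported EGR1 target genes had a median of 0.25 at 3 h (2.83e-02), with 10 of 19 higher, including Ptges (3.43), Mad2l1 (3.04), Icam1 (1.87) and Vegfa (1.86), and a median of 0.21 at 6 h (1.67e-02).

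Ribosome biogenesis genes rose almost throughout in WT, 23 of 25 at 3 h (24 adjusted over the list alone; median 0.88, camera adjusted p = 8.08e-13) and 24 at 6 h (0.95, 3.02e-14), led by Rrp12, Nop58 and Ddx21. Unfolded protein response genes rose in 11 of 19 cases at 3 h (0.59, 1.73e-03; 0.37 without the second WT 0 h array) and in 16 at 6 h (17 adjusted over the list alone; 1.10, 5.11e-07), with Trib3 (2.63) and Atf4 (1.39) at 3 h and Creld2 (2.66) and Dnajc3 (1.71) at 6 h. Cholesterol synthesis genes followed at 6 h, when 12 of 16 rose (13 adjusted over the list alone; 0.70, 1.38e-05), with Hsd17b7 (1.71) and Sqle (1.62) in front. None of the 107 list calls in this work held when camera estimated the correlation between genes. For the ribosome list at 3 h the adjusted p was then 1.79e-01.

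The largest falls in WT were those of the clock output gene Dbp (-3.04 ± 0.20 SE at 3 h, adjusted p = 4.76e-08; -3.54 at 6 h), Nrep (-2.73), Klhl24 (-2.61), Tril (-2.59), Cldn1 (-2.46), Sesn1 (-2.44), Msc (-2.44), the Wnt agonist gene Rspo3 (-2.31) and, at 6 h, Ypel3 (-3.48) and Bdh2 (-2.78). Wnt signalling genes fell in 12 of 23 cases at 3 h (median -0.31, camera adjusted p = 2.46e-02) and in 11 at 6 h (-0.16, 5.96e-03), with Sfrp2 (-2.20) and Dkk3 (-2.07) at 6 h. Of 25 extracellular matrix genes 14 fell at 3 h (-0.34, 6.36e-03) and 14 at 6 h (-0.67, 7.19e-03), including Col1a1 (-2.03), Lum (-1.83) and Col3a1 (-1.75) at 3 h. Without the first WT 0 h array the matrix calls were lost at 3 h (6.21e-02) and at 6 h (6.81e-02), although the medians stayed at -0.39 and -0.53. The call of lower mitosis genes at 6 h (median -0.36, 2.97e-02) was lost without that array, with a median of -0.06. Without the second WT 6 h array that mitosis call was lost too (5.74e-02). Steroid and nuclear receptor genes fell at 6 h (-0.29, 2.02e-02; -0.10, 4.62e-02 without the second WT 0 h array), led by Nr1d2 (-1.89), while Pgr rose (1.11). Adipocyte markers fell in 7 of 8 cases at 3 h (-1.23, 3.88e-02) and 6 of 8 at 6 h (-1.41; adjusted p = 5.01e-01 with an estimated correlation), and Adipoq (-3.64), Scd1 (-3.33), Cyp2e1 (-3.06), Car3 (-2.99) and Cdo1 (-2.77) were among the largest falls at 6 h. The adipocyte call at 3 h was lost without the second WT 0 h array (9.18e-02), the first WT 3 h array (6.43e-02) or replicate 3 of that group (7.05e-02). Mesothelial markers also fell at 6 h in 6 of 7 cases (-0.32).

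The same question in KO uteri gave a response of much the same genes. At 3 h 5952 genes passed the test, 2803 higher and 3149 lower, and 659 changed at least 2-fold. At 6 h there were 6613, 3218 higher and 3395 lower, with 970 at least 2-fold. No array is shared between the genotypes' responses. Across genes the KO and WT changes correlated at r = 0.903 at 3 h and 0.921 at 6 h, where genes are not independent replicates. The same direction was called in both for 5016 genes at 3 h and 5328 at 6 h, and opposite directions for 24 and 15. Independent lists of these sizes would share 622 higher and 771 lower genes at 3 h, against 2371 and 2645 shared, and 705 and 750 at 6 h, against 2640 and 2688.

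Among the largest rises in KO were Phf21b (3.96 ± 0.18 SE at 3 h, adjusted p = 1.12e-08), Chac1 (3.75), Socs3 (3.69), Klk1b5 (3.64), Ptges (3.25), P4ha2 (3.24) and, at 6 h, Slc6a13 (3.15), Mthfd2 (3.07), Adamts4 (2.85) and Tmem200a (2.77). Klk1b26 (3.41 at 3 h, 2.96 at 6 h) has another probe of the opposite sign at both times. Among the largest falls were Rspo3 (-2.78 ± 0.12 at 3 h, 8.77e-09), Sesn1 (-2.69), C2cd4a (-2.78), Dbp (-2.47), Hp (-2.80) and, at 6 h, Klhl24 (-3.19), Ypel3 (-3.09), Fam214a (-3.03) and Tsc22d3 (-2.76). C2cd4a has a probe of the opposite sign. The fall of Cyp2e1 at 3 h (-3.62, 3.51e-03) did not pass without the first KO 3 h array (-2.52). Immediate-early genes rose in 16 of 25 cases at 3 h (median 0.54, camera adjusted p = 1.84e-06) and 13 at 6 h (0.31, 1.25e-03). Ribosome biogenesis genes rose in 21 of 25 cases at 3 h (0.78, 8.62e-12) and 23 at 6 h (0.91, 2.02e-13). Unfolded protein response genes rose in 10 of 19 and then 16 cases (0.51 at 3 h, or 0.25 without the first KO 3 h array, and 0.81 at 6 h, 1.77e-05), and cholesterol synthesis genes in 8 of 16 and then 13 (0.83, 1.77e-05). Early estrogen-response genes had a median of 0.63 at 3 h (2.21e-05) and 0.81 at 6 h (2.06e-05), with Greb1 (3.03) and Vegfa (2.20) in front at 3 h. The EGR1 target list had a median of -0.04 and a mean of 0.48 at 3 h and was not called, although fry called it higher (1.15e-06), and it was called at 6 h (0.28, 3.83e-02) except without the first KO 6 h array (5.71e-02). Matrix genes were called lower at 3 h (-0.47, 1.11e-02) and at 6 h (-0.49, 3.83e-02), the latter not without the second KO 0 h array (8.23e-02) or the second KO 6 h array (1.70e-01). All 8 adipocyte markers fell at 3 h (-1.71, 2.35e-03) and at 6 h (-1.63, 5.71e-03). Late secretory genes were called higher at 6 h (0.35, 3.83e-02), but not without the first KO 0 h array (1.50e-01) or the second KO 6 h array (5.93e-02). Steroid and nuclear receptor genes were called lower (-0.24, 4.99e-02), but not without the first KO 0 h array (7.31e-02) or either KO 6 h array (5.41e-02 and 6.57e-02), and mesothelial markers (-0.26, 2.45e-02), but not without the second KO 0 h array (5.26e-02) or the first KO 6 h array (5.41e-02).

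At 24 h the question is the later response to E2, first in WT uteri. In WT 5582 genes passed the test, 2781 higher and 2801 lower, and 471 changed at least 2-fold. Without the second WT 0 h array 3681 passed. Without the first WT 0 h array, 753 changed at least 2-fold. Late estrogen-response secretory genes rose in 18 of 22 cases in WT (median 1.36, camera adjusted p = 1.06e-09; 9.31e-02 with an estimated correlation), led by Sprr2f (3.16 ± 0.50 SE, adjusted p = 2.32e-04), Lcn2 (2.88 ± 0.34, 2.28e-05), Ltf (2.80 ± 0.31, 1.48e-05) and Chil1 (2.77 ± 0.23, 2.07e-06). Sprr2f and Sprr2g (2.65) belong to a family of near-identical genes and are uncertain as single genes. Bace2 (2.75), Car12 (2.63), Aoc1 (2.55), Padi1 (2.53) and Ckmt1 (2.52) also had large rises. Of 15 epithelial markers 10 rose (median 0.43, 4.67e-05), with Krt7 (2.20), Elf3 (1.87) and Krt19 (1.25) ahead.

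DNA replication genes rose in 19 of 29 cases in WT at 24 h (26 adjusted over the list alone; median 0.51, camera adjusted p = 9.21e-07), among them Uhrf1 (1.36), Tk1 (1.27), Rrm1 (1.14) and Mcm10 (1.11), and mitosis genes in 18 of 25 (1.06, 9.21e-07), among them Mad2l1 (1.67), Cdc20 (1.63) and Plk1 (1.56). The replication rise depended on the arrays: its median was 0.75 with 27 members higher without the first WT 0 h array, 0.26 with 5 higher without the second (4.31e-04), and 0.36 with 6 higher without the first WT 24 h array (6.75e-05). The mitosis median was 1.47 without the first WT 0 h array and 0.67 without the second. Cholesterol synthesis genes rose in 15 of 16 cases (1.03, 2.56e-11), with Fdps (2.14) and Msmo1 (2.09) in front, glycolysis genes in 9 of 14 (0.53, 3.46e-05), and ribosome biogenesis genes in 19 of 25 (0.31, 2.35e-06). The largest falls in WT were those of Inmt (-4.14 ± 0.25 SE, adjusted p = 2.82e-07), Tgfbi (-3.17), Pamr1 (-3.11), Galnt15 (-2.76), Plat (-2.74) and Cdh16 (-2.49), with the fat-cell genes Adipoq (-3.04) and Lpl (-2.99). Wnt signalling genes fell in 13 of 23 cases (-0.32, 2.03e-05), endothelial markers in 9 of 13 (-0.48, 6.44e-04) and adipocyte markers in 6 of 8 (-1.41, 3.43e-03). Progesterone-response genes were called lower (-0.21, 2.25e-02), but not without the first WT 0 h array (1.29e-01). Smooth muscle (0.20, 1.25e-01) and stromal fibroblast markers (-0.22, 1.60e-01) were not called.

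In KO at 24 h 6730 genes passed the test, 3319 higher and 3411 lower, and 979 changed at least 2-fold. All 29 DNA replication genes rose in KO (median 1.57, camera adjusted p = 1.27e-15), led by Uhrf1 (3.48 ± 0.48 SE, adjusted p = 3.48e-05), Tk1 (2.80 ± 0.31, 5.91e-06), Mcm5 (2.80 ± 0.30, 4.69e-06) and Mcm10 (2.61). Mitosis genes rose in 20 of 25 cases (1.43, 2.96e-07), with Prc1 (2.69) and Top2a (2.55) ahead, and Pbk (3.11) and Pclaf (3.01) were among the largest rises. Late secretory genes rose in 12 of 22 cases and fell in 3 (0.81, 6.12e-03). Cholesterol synthesis genes rose in 15 of 16 (1.21, 1.21e-09), ribosome biogenesis genes in 22 of 25 (0.63, 7.77e-10), and glycolysis genes in 9 of 14 (0.40, 2.54e-03). Wnt signalling genes fell in 13 of 23 (-0.25, 2.99e-03). Macrophage markers fell in 13 of 14 cases (-0.98, 5.67e-04), including Lyz2 (-1.58), Cd163 (-1.52) and Laptm5 (-1.40), but without the second KO 0 h array 5 fell and the median was -0.48 (7.60e-03). All 8 adipocyte markers fell (-1.84, 1.22e-03), beside the large falls of Cyp2e1 (-4.79), Adipoq (-3.73), Car3 (-3.50) and Ces1d (-3.52). Inmt (-3.69), Galnt15 (-3.63), Amy2a5 (-3.55), Sult1a1 (-3.27) and Tgfbi (-3.25) fell as well. The matrix list had a median of 0.24 while its test pointed lower and was not called (9.79e-01), and Col1a1 rose (2.37).

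**Figure D2:**
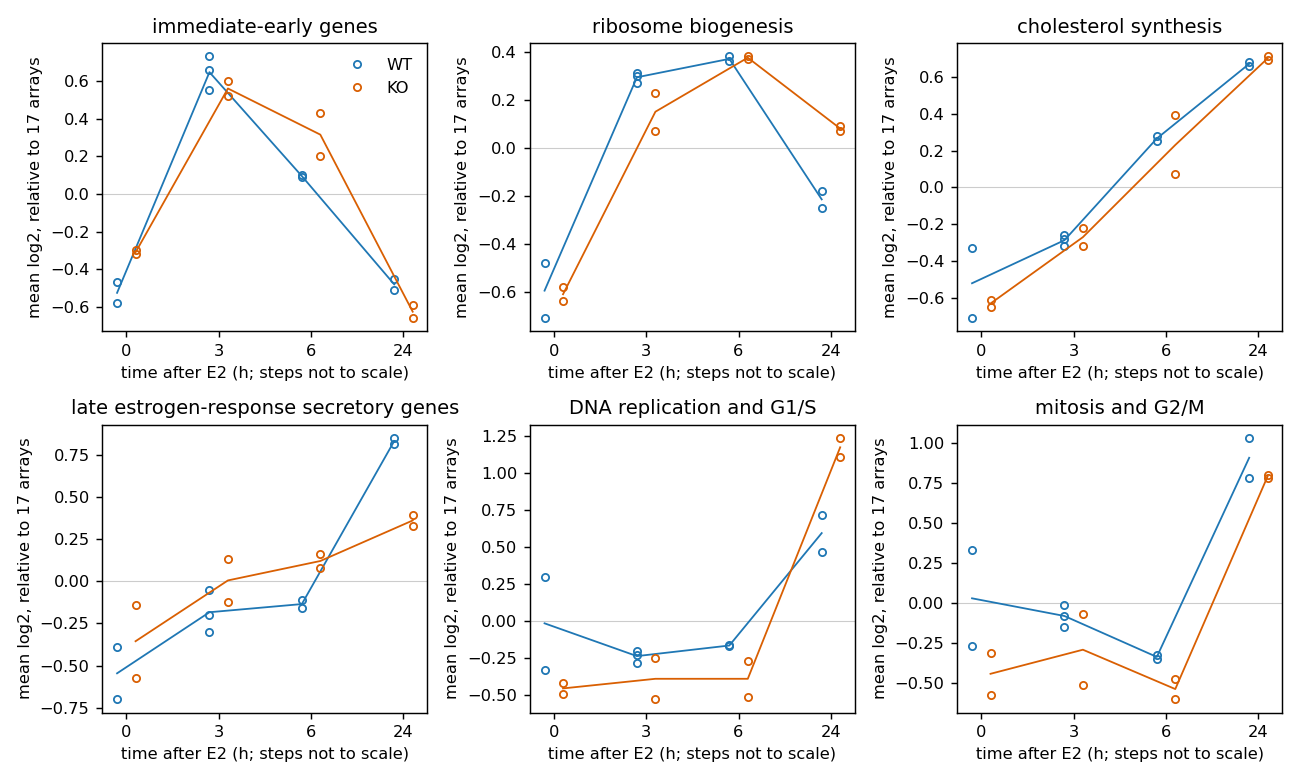
Mean log2 value of 6 gene lists on each array (points), relative to the 17 arrays, with group means (lines) in WT and KO, against hours since E2; the time axis is not to scale. The replication list reaches 1.11 and 1.24 in the KO 24 h arrays against 0.47 and 0.72 in the WT 24 h arrays, and the first WT 0 h array lies at 0.30.

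Whether the response differed between the genotypes was asked with the interaction. The interaction also takes in any difference between KO and WT at 0 h, with its sign reversed. It passed jointly for 1006 genes. At 24 h 1071 genes passed, 607 with a higher and 464 with a lower change in KO, against 161 at 3 h and 59 at 6 h. Across genes the 24 h changes of KO and WT correlated at r = 0.832. Their slope by total least squares, which treats both changes alike, was 1.37 (1.10 without the first WT 0 h array and 1.75 without the second). The same slope was 0.934 at 3 h and 1.04 at 6 h. At 24 h 4480 genes were called in the same direction in both genotypes and 69 in opposite directions. Expected from independent lists were 626 shared higher and 648 shared lower genes, against 2224 and 2256. The joint count moved with single arrays: it was 282 without the second and 329 without the first WT 24 h array, 325 without the second and 338 without the first KO 24 h array, 485 and 497 without the first and second WT 6 h array, 540 without the second KO 0 h array, and 665 without the second WT 3 h array. It was 1755 without the first KO 3 h array and 2220 without the second WT 0 h array. Without the first WT 0 h array 533 genes passed at 24 h, 83 at 3 h and 38 at 6 h.

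Replication genes had a larger rise in KO at 24 h in 21 of 29 cases (27 adjusted over the list alone; median interaction 0.91, camera adjusted p = 1.48e-20; 4.09e-01 with an estimated correlation), including Mcm5 (1.86 ± 0.43 SE, adjusted p = 2.05e-02) and E2f1 (1.54). The number of members past the test was 5 without the second WT 24 h array, 8 without the first KO 24 h array, 12 without the second, 10 without the second KO 0 h array, 12 without the first and 13 without the first WT 0 h array, and the median stayed between 0.71 and 1.22 whichever array of these groups was left out. Ribosome biogenesis genes had a median of 0.31 (9.14e-07). The mitosis list was called (0.31, 1.95e-02) with 1 member past the test, but not without the first WT 0 h array (median 0.04), the first KO 0 h array (0.13) or the first WT 24 h array (0.08). Smaller rises or larger falls in KO were found for late secretory genes (-0.52, 2.59e-05), immediate-early genes (-0.21, 1.72e-04) and macrophage markers (-0.96, 2.96e-06; 3 of 14 past the test), and epithelial markers were called lower (-0.08, 2.15e-02) except without the second WT 0 h array (2.08e-01). Without the second KO 0 h array the macrophage median was -0.50 (5.34e-04) with 0 members past the test, and the late secretory median was -0.26, against -0.22 without the second WT 0 h array (2.27e-02). Granulocyte markers were called lower (-0.29, 5.48e-03; -0.08, 2.97e-02 without the second KO 0 h array). Lymphocyte markers (-0.49, 1.95e-02) lost their call without the second KO 0 h array (9.43e-02) or the second WT 0 h array (7.95e-02). Interferon-stimulated genes (-0.39, 1.51e-02) lost theirs without either of these (medians of -0.35 and -0.45), the first KO 24 h array (7.84e-02) or the first WT 24 h array (1.70e-01). Named by the rule for 24 h were Serpinb11 (2.55), Slc6a2 (1.95), Rad54b (1.89) and H2ac12 (1.82) upward, and Ccl21c (-3.02), Slpi (-2.74), Ccl21a (-2.55), Hp (-2.32) and Gsta3 (-2.31) downward. Cxcl17 (-1.70), Alpl (-1.32) and Sprr2e (1.35) were among the 10 genes with the smallest joint p-value.

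**Figure D3:**
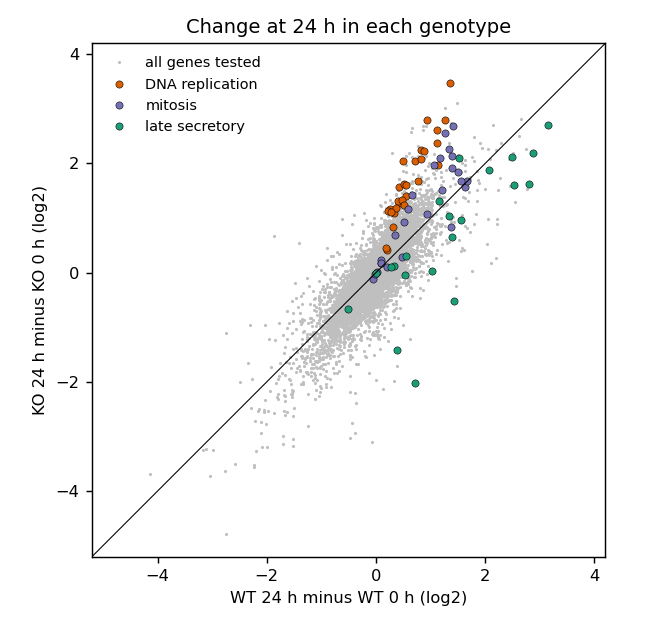
Change at 24 h against 0 h in WT (x axis) and KO (y axis), log2, for every gene tested, with the replication, mitosis and late secretory lists in colour and a line of equal change. The replication genes lie above the line, with medians of 0.51 in WT (0.75 without the first WT 0 h array) and 1.57 in KO.

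At 3 h the interaction was lower for immediate-early genes (median -0.21, camera adjusted p = 1.04e-05; 4.30e-01 with an estimated correlation), with 3 of 25 members past the test, including Egr3 (-1.08), for the EGR1 target list (-0.13, 1.29e-02), with Pdgfb (-0.71) and Icam1 (-0.71), and for early estrogen-response genes (-0.23, 1.24e-02), the last not without the second KO 3 h array (6.32e-02) or the second WT 0 h array (1.86e-01). It was also lower for ribosome biogenesis genes (-0.11, 1.24e-02), but not without the second KO 3 h array (3.99e-01) or the second WT 0 h array (8.60e-01), and for granulocyte markers (-0.34, 1.24e-02), but not without the second KO 0 h array (median -0.01) or the first WT 0 h array (5.09e-02). Lymphocyte (-0.37, 1.94e-02) and adipocyte markers (-0.42, 4.17e-02) were called lower and lost the call without the second KO 0 h array (1.46e-01 and 1.24e-01), the first KO 3 h array (3.21e-01 and 7.93e-01), the first WT 0 h array (5.09e-02 and 2.17e-01) or the second WT 3 h array (6.45e-02 and 1.53e-01), and the lymphocyte call without the second WT 0 h array (7.64e-02). Single genes with a smaller or opposite change in KO at 3 h were Pdk4 (-1.56 ± 0.27 SE, adjusted p = 1.58e-02), Slc6a13 (-1.30), Has1 (-1.29) and Hif3a (-1.26), and those with a larger one were Gcnt3 (1.47), Serpina1e (1.27), Sned1 (1.15) and Srek1 (1.35 ± 0.09, 1.86e-05). Lpp (1.55) and Srek1 each have a probe of the opposite sign. At 6 h Hpgds (-1.83 ± 0.18, 5.90e-04), Tfcp2l1 (-1.42), Cldn3 (-1.33), Slc25a33 (-1.33) and Pde6h (-1.33) had a lower change in KO, and Slc7a11 (1.5, with a probe of the opposite sign), Slc40a1 (1.25), Phlda1 (1.24), Cxcl14 (1.22) and Wnt7a (1.08) a higher one. The replication and mitosis lists were called higher at 3 h (0.23 and 0.26) and at 6 h (0.21 and 0.28). Without the first WT 0 h array these medians were 0, -0.04 at 3 h and -0.10, -0.03 at 6 h, and none was called. The replication call at 3 h was also lost without the second KO 3 h array (8.21e-02), and the mitosis call without that array (5.73e-01), the first KO 0 h array (1.80e-01) or the second WT 3 h array (7.48e-02). The 6 h calls were lost without the first KO 0 h array (6.02e-02 and 2.01e-01), the first KO 6 h array (3.94e-01 and 1.01e-01) or the second WT 6 h array (6.94e-02 for both), and the replication call without the first WT 6 h array (7.09e-02).

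The next question is how KO differed from WT before E2. At 0 h 653 genes passed the test, 330 higher and 323 lower in KO, and 49 differed at least 2-fold. The count was 183 without the second and 372 without the first KO 0 h array, 254 without the first and 1720 without the second WT 0 h array. Dlk1 was higher by 3.55 ± 0.46 SE (limma, adjusted p = 1.10e-03), followed by Hp (2.05), Wfikkn2 (1.88 ± 0.23, 7.33e-04), Hif3a (1.66, with a probe of the opposite sign), Hpgds (1.65 ± 0.13, 2.17e-05), Prap1 (1.65), Cd163 (1.47), Bex4 (1.43), Moxd1 (1.39) and Coch (1.36). Igf2 was higher by 1.35. Lower in KO were Serpinb11 (-2.32 ± 0.37, 3.61e-03), Cxcl15 (-1.73), Rasgrf1 (-1.73), Cxcl14 (-1.68 ± 0.11, 1.36e-05), Slc7a11 (-1.43), Wif1 (-1.41), Sp5 (-1.38), P2ry14 (-1.35), Tns4 (-1.30) and Atp10b (-1.30). Immediate-early genes were called higher (median 0.18, camera adjusted p = 5.09e-05), with Ccn2 (0.92) and Ccn1 (0.44) past the gene test. Replication (-0.39, 8.30e-09) and mitosis genes (-0.45, 3.03e-06) were called lower with 1 member each past the gene test, and without the first WT 0 h array their medians were -0.16 (7.14e-02) and -0.11 (1.24e-01). Macrophage (0.51, 5.09e-05), granulocyte (0.25, 1.15e-03), lymphocyte (0.41, 6.44e-03) and mesothelial markers (0.06, 3.54e-02) were called higher. Without the second KO 0 h array their medians were 0.07, 0.04, 0.19 and 0.02 and none was called. The lymphocyte call was also lost without the second WT 0 h array (5.37e-02) and the mesothelial call without the first (1.08e-01). Adipocyte markers were called higher (0.52, 1.72e-03) with 0 of 8 past the gene test and 4 adjusted over the list alone.

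At 3 h 624 genes differed between the genotypes, 319 higher and 305 lower in KO, and 22 at least 2-fold. The count was 198 without the second and 1139 without the first KO 3 h array, and 385 and 305 without replicates 2 and 3 of WT 3 h. Higher in KO were Prap1 (1.78 ± 0.23 SE, adjusted p = 1.49e-03), Ltf (1.67), Dlk1 (1.64), Clca1 (1.58), Wfikkn2 (1.13), Txnip (0.99), Klk1b24 (0.95), Nt5e (0.89), Syne2 (0.98) and Wapl (0.84), the last 2 of which have a probe of the opposite sign. Lower in KO were Ddit4l (-1.62), Krt23 (-1.58 ± 0.14, 1.86e-04), Cxcl15 (-1.55), Wfdc15b (-1.47), P2ry14 (-1.44), Serpinb11 (-1.35), Ramp3 (-1.32), Sp5 (-1.26), Wif1 (-1.20) and Rasgrf1 (-1.20). The EGR1 target list was lower (median -0.08, camera adjusted p = 1.35e-02; 1.55e-01 with an estimated correlation; fry 4.63e-05), with 4 of 19 members lower and 1 higher (7 and 1 adjusted over the list alone), among them Pdgfb (-0.73), Kit (-0.71) and, higher, Igf2 (0.74). Egr3 (-0.94) and Egr2 (-0.90) were lower. Ribosome biogenesis genes were called lower (-0.15, 5.05e-04), but not without the second KO 3 h array (1.64e-01). Macrophage markers were called higher (0.24, 4.26e-02), but not without the second KO 3 h array (median -0.03), the first WT 3 h array (5.61e-02) or the second (7.61e-02). Interferon-stimulated genes had a median of 0.16 (2.80e-01), of 0.47 without the first KO 3 h array (1.54e-08) and of -0.21 without the second (8.94e-05).

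At 6 h 93 genes differed, 40 higher and 53 lower in KO, and 8 at least 2-fold. The count was 0 without the first and 8 without the second WT 6 h array, and 589 and 16 without the first and second KO 6 h array; 1743 genes had an unadjusted limma p under 0.05 in the fit of all arrays. Higher in KO were Ltf (1.77 ± 0.31 SE, adjusted p = 2.43e-02), Arhgap35 (0.87), Phlda1 (0.78), Gdnf (0.75), Chil5 (0.75), Cxcl1 (0.74), Pglyrp1 (0.74, with a probe of the opposite sign), Urah (0.70), Uox (0.69) and Ccnd3 (0.67). Lower were Wfdc15b (-1.42, 2.43e-02), Aldh1a1 (-1.22), Atp10b (-1.21), the epithelial signal gene Ihh (-1.10 ± 0.11, 1.13e-03), Gstm7 (-1.10), Dclk3 (-1.07), Prr15l (-1.01, with a probe of the opposite sign), Cldn3 (-0.98), Cldn1 (-0.94) and Cdh16 (-0.91). The calls of Ltf and Wfdc15b were lost without the second KO 6 h array (1.68 and -0.91), the first WT 6 h array (1.92 and -1.33) or the second (1.62 and -1.51). Immediate-early genes were called higher (median 0.16, camera adjusted p = 3.64e-05; 0.08, 3.30e-02 without the second KO 6 h array), with 0 of 25 past the gene test and 6 adjusted over the list alone. Replication (-0.22, 2.17e-03) and unfolded protein response genes (-0.25, 1.05e-02) were called lower and adipocyte (0.36, 1.05e-02) and mesothelial markers (0.10, 1.05e-02) higher, and these 4 calls were lost without the second KO 6 h array (medians of -0.10, -0.12, 0.02 and 0.07). Macrophage markers (0.29, 6.81e-03) lost their call without the first KO 6 h array (6.29e-02). The adipocyte call was also lost without the first WT 6 h array (5.46e-02) and the mesothelial call without the second (1.09e-01).

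At 24 h the test passed 1231 genes, 601 higher and 630 lower in KO, and 52 differed at least 2-fold. This is the highest count of the 4 times with all arrays. Leaving out any of the 4 arrays compared lowered it, to within the range of such counts at each other time. Replication genes were higher in 17 of 29 cases (24 adjusted over the list alone), with a median of 0.61 (camera adjusted p = 1.18e-16; 2.91e-01 with an estimated correlation; fry 3.08e-02), and E2f1 (0.99) and Cdc6 (0.84) were the members named. The number past the test was 2 without the first KO 24 h array, 5 without the second, 11 without the first WT 24 h array and 2 without the second, with medians from 0.50 to 0.72. Ribosome biogenesis genes were higher in 11 of 25 cases (13 adjusted over the list alone; 0.27, 3.23e-11), with Nop58 (0.57) and Rrp12 (0.53) in front. Late secretory genes were lower in 5 of 22 cases and higher in 1 (9 and 1 adjusted over the list alone; -0.44, 9.33e-06), with Pigr (-1.35), Lcn2 (-1.21) and Lrg1 (-0.93) lower. Interferon-stimulated genes (-0.43, 1.30e-05; -0.25 without the first WT 24 h array), with 3 of 23 lower, among them Usp18 (-0.93), and epithelial markers (-0.20, 1.79e-04), with 2 of 15 lower, among them Cdh1 (-0.65), were called lower. Chemokines and cytokines (-0.07, 2.22e-02), with Ccl11 (-1.45), were called lower except without the first KO 24 h array (6.44e-02) or the first WT 24 h array (5.79e-02), and macrophage markers (-0.31, 7.39e-03), with Laptm5 (-1.11) and Cd14 (-0.82), except without the same arrays (6.44e-02 and 5.79e-02).

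The largest single differences at 24 h were the higher Bex4 (2.01 ± 0.19 SE, adjusted p = 5.65e-05), Dlk1 (1.84), Egr1, Sprr2e (1.43), Inmt (1.28), the cyclin gene Ccnd2 (1.26 ± 0.11, 2.92e-05), Maob (1.24), Slc6a2 (1.23), Stc1 (1.10) and Ldoc1 (1.10), and the lower chemokine genes Ccl21c (-2.41 ± 0.21, 3.59e-05) and Ccl21a (-2.21), Rasgrf1 (-2.17), Atp10b (-1.94), Acta1 (-1.82), Bpifb5 (-1.75), Gpnmb (-1.72, with a probe of the opposite sign), Hgfac (-1.59), Tmprss11a (-1.58) and Aoc1 (-1.58). Ccl21a and Ccl21c are near-identical, and so are the Sprr2 genes, so single members of each are uncertain. Igf2 was higher by 0.97, Nr2f2 by 0.92, and Kit was lower by -0.85.

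Averaged over the 4 times, 1331 genes differed between KO and WT, 599 higher and 732 lower in KO, of which 12 differed at least 2-fold. Of the called genes 266 had groups that did not overlap at any time, and 272 (1.85%) of all genes tested did so, where chance gives 0.0926%. Higher in KO at every time were Dlk1 (2.23 ± 0.22 SE, adjusted p = 6.40e-05), Bex4 (1.24 ± 0.09, 7.63e-06), Wfikkn2 (1.09), Moxd1 (1.00), Clca1 (0.92), Inmt (0.77), Aqp1 (0.68), Upk3bl (0.67), Ccnd3 (0.66) and Ccnd2 (0.65). Lower at every time were Rasgrf1 (-1.53 ± 0.13, 1.91e-05), Cxcl15 (-1.29), Wfdc15b (-1.19), P2ry14 (-1.06), Ddit4l (-1.04), Cxcl14 (-0.94 ± 0.06, 2.34e-06), Sp5 (-0.91), St6gal1 (-0.89), Ppp1r1b (-0.85) and Sel1l3 (-0.84). Igf2 (0.85), Kit (-0.65) and Mmp14 (-0.38) differed among the reported EGR1 targets, a list with a median of -0.02 (camera adjusted p = 2.20e-01). Ihh (-0.50), Ramp3 (-0.74) and Wif1 (-0.90) were lower and Nr2f2 (0.41) higher. Mitosis genes were called lower (-0.17, 1.60e-04), with 6 of 25 past the gene test (-0.11 with 2 past it without the first WT 0 h array), and adipocyte markers higher (0.29, 8.12e-03; 0.18, 4.44e-02 without the second KO 6 h array). Macrophage markers (0.14, 3.18e-02) were called higher, but not without the second KO array of 0 h (1.81e-01), 3 h (2.57e-01) or 24 h (9.94e-02), the first KO 6 h array (5.93e-02), the first WT array of 0 h (6.16e-02) or 6 h (5.72e-02), or the second WT array of 3 h (6.62e-02) or 24 h (6.86e-02). Mesothelial markers (0.06, 1.79e-02) were not called without the second KO 0 h array (7.21e-02).

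**Figure D4:**
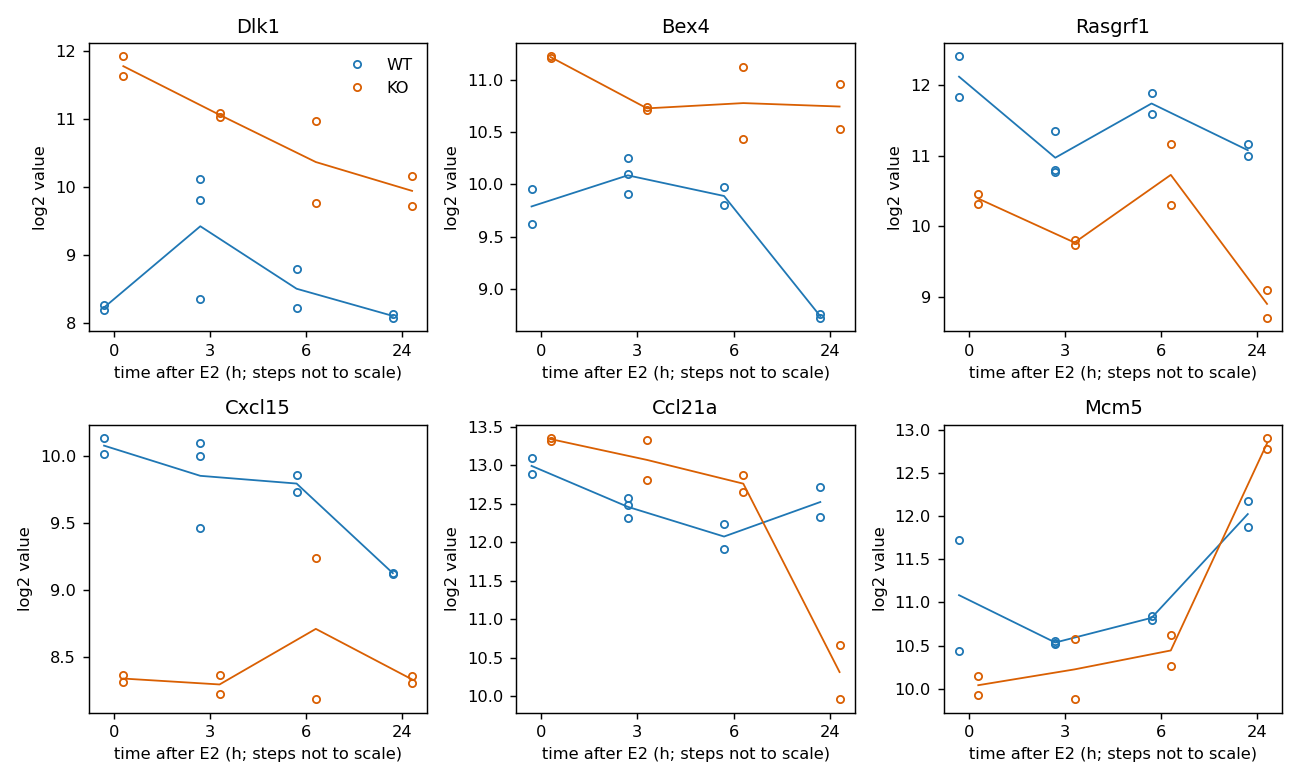
Log2 value of Dlk1, Bex4, Rasgrf1, Cxcl15, Ccl21a and Mcm5 on each array (points) with group means (lines) in WT and KO, against hours since E2; the time axis is not to scale. Dlk1 and Bex4 lie higher and Rasgrf1 and Cxcl15 lower in KO at every time, while Ccl21a falls to its lowest values in KO at 24 h.

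The genotype differences at the separate times were compared across genes, and no arrays are shared between times. They correlated at r = 0.394 between 0 and 3 h, 0.420 between 0 and 6 h and 0.395 between 3 and 6 h, but at -0.00291 between 0 and 24 h, 0.0705 between 3 and 24 h and 0.0903 between 6 and 24 h. Genes called at 2 times still had the same direction more often than opposite ones. The tests at all times share each gene's spread, so their lists of called genes are not independent. An excess over the count expected from independent lists therefore does not by itself show a lasting direction. At 0 and 24 h 99 had the same direction and 54 opposite ones, where 27.3 with the same were expected, at 3 and 24 h 98 and 28 (26.0 expected), and at 6 and 24 h 23 and 11 (3.90 expected). Of the 14737 genes 1789 were called at 1 time, 324 at 2, 48 at 3 and 5 at all 4. The 5 were Arg2 (-0.51, -0.91, -0.75 and -0.66 in the order of the times), Ccnd3 (0.60, 0.39, 0.67 and 0.99), Csrp2 (0.38, 0.32, 0.52 and 0.43), Gpc3 (0.58, 0.55, 0.61 and 0.60) and Srek1, which was lower at 0 h (-0.55) and higher later (0.80, 0.53 and 0.78). They were chosen after their values were seen. Among the marker lists too short to test, 0 of 3 erythroid markers were called in any comparison (-0.86 to 0.39), and 4 ovary and oviduct markers gave 2 calls (-0.67 to 0.48 over all comparisons), Ovgp1 in KO at 24 h (-0.67) and Inha in KO at 6 h (-0.20).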

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

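The tests of the first WT 0 h array, of cycling cells, of epithelium, of the time of day and of linkage as the whole cause were chosen only after the result was seen. The counts and genes of this and the next paragraph were picked out because a test of the difference itself, the genotype by time interaction, passed. For them the change since 0 h differed between KO and WT by that test. The limits given above for single arrays and for other probes of a gene hold here too. Dbp and the genotype differences present at every time, weighed further below, were not picked by that test. Groups of 2 or 3 arrays are too small for an outlier test. The interaction passed for 161 genes at 3 h, 59 at 6 h and 1071 at 24 h, and for 1006 genes in the joint test.

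At 3 h the change in KO exceeded that in WT for Lpp (1.55), Gcnt3 (1.47), Srek1 (1.35), Serpina1e (1.27) and Sned1 (1.15) and lay below it for Pdk4 (-1.56), Egr1 (-1.33), Slc6a13 (-1.30), Has1 (-1.29) and Hif3a (-1.26). At 6 h it was larger for Slc7a11 (1.5), Slc40a1 (1.25), Phlda1 (1.24), Cxcl14 (1.22) and Wnt7a (1.08) and smaller for Hpgds (-1.83), Tfcp2l1 (-1.42), Pde6h (-1.33), Cldn3 (-1.33) and Slc25a33 (-1.33). At 24 h it was larger for Serpinb11 (2.55), Slc6a2 (1.95), Rad54b (1.89), Mcm5 (1.86), H2ac12 (1.82) and Sprr2e (1.35) and smaller for Ccl21c (-3.02), Slpi (-2.74), Ccl21a (-2.55), Hp (-2.32), Gsta3 (-2.31), Hpgds (-1.83), Cxcl17 (-1.70) and Alpl (-1.32). Those also named by the rule at 0 h all differed there in the opposite direction. Serpinb11 (-2.32), Slc7a11 (-1.43) and Cxcl14 (-1.68) were lower in KO at 0 h, and Hp (2.05), Hpgds (1.65) and Hif3a (1.66) higher. For these genes the interaction takes in that 0 h difference, so it need not show a different response to E2.

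The replication genes rose more in KO than in WT at 24 h. The first WT 0 h array as the whole cause is excluded, since the direct KO against WT difference at 24 h, which uses no 0 h array, had a median of 0.61 (0.55 to 0.66 in a bootstrap over its genes, which leaves out the spread between arrays, and 0.50 to 0.72 with 1 array of 24 h left out), while without that array 13 of 29 members, against 21, passed the interaction test. A larger share of cycling cells, spread over the cycle as in WT, would raise the mitosis list alike. That list's median was -0.12 (-0.15 to 0.04 in the bootstrap, -0.24 to 0.02 with 1 array left out). A larger share of cells in replication alone need not raise it and stays open. A larger share of epithelium would raise epithelial markers, whose median was -0.20 (-0.33 to -0.00107 and -0.25 to -0.16). Epithelial markers themselves rose after E2 in WT at 24 h, so their level does not measure that share alone. A delayed response in KO stays open: outside the cell cycle lists KO minus 1 WT 24 h array correlated across 14683 genes with the other WT 24 h array minus WT 6 h at -0.174 and, with the WT arrays exchanged, -0.211. A delay needs this sign, but a deviation shared by both WT 24 h arrays gives it too, so the sign cannot decide. By the total least squares slope, the 24 h response as a whole was not weaker in KO (1.37, and 1.10 to 1.75 with 1 array left out). That slope is not a regression of KO on WT. A weaker response of part of the late genes also predicts the same sign, and times between 6 and 24 h were not measured.

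Dbp fell in both genotypes at 3 and 6 h, and the time of day could account for it. The 8 other clock genes driven by E-boxes or D-boxes had a median change at 6 h of -0.69 in WT and -1.14 in KO, while 3 genes of the Bmal1 group moved the other way (0.36 and 0.54). At 24 h, when a daily rhythm would have returned to its start, the first group still lay at -0.51 in WT and -0.92 in KO, while Dbp had come back to -0.81 and -1.05. Time of day and E2 cannot be told apart for these genes, because no array of the 17 carries a later time without E2.

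Genotype differences averaged over the 4 times could come from genes that travel with the disrupted Egr1 in breeding. The tests here used the average comparison, whose 1331 called genes need not differ at every time. Of these, 266 had groups that did not overlap at any time. A change confined to genes on the chromosome of Egr1 is excluded as the whole cause. Of the genes called in the average comparison 2.55% (1.78 to 3.55) lie there, where 2.49% of the tested genes lie (gene order from assembly GRCm38). Linked genes that change genes elsewhere need not raise this share, so linkage itself is not excluded. Nearby genes as a part of the cause stay open: of the 50 nearest tested genes on each side 12% were called, against 9.01% of the others (Fisher exact test, p = 0.292, odds ratio 1.38, 0.684 to 2.54), while the nearest 20 held no called gene (-0.09 to 0.22, lowest adjusted p = 1.71e-01). Because Dlk1, Igf2 and Rasgrf1 are imprinted, 30 other imprinted genes were tested as a class, and their median absolute difference lay at percentile 97.4 of random lists, above the 95 that would have spoken against the class and just short of the bound set for it, which leaves the class open. No strain or litter is given in the sources used here.

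Other splits of the arrays within each time were counted, 100 drawn of 2160. For the average comparison 1 of 100 splits, the real one, gave as many as 1331 genes. The highest other gave 580, and the median of the others was 0. A split that mixes arrays of different groups adds any difference between those groups to the spread. If arrays of a group came from the same animal, this alone yields few genes, so the count does not exclude chance. For the joint interaction 2 of 100 splits gave as many as the real 1006, and the highest other gave 2004. That split keeps the real groups at all 4 times and exchanges the names of KO and WT at 0 and 24 h only, so it turns lasting genotype differences into interactions.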

How the results depend on the processing

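Cyclic loess, the first WT 0 h array left out, crossed numbers, and the list tests under other filters and without each array were tests chosen only after the result was seen. The number of arrays limits these results, and leaving out 1 array of 2 leaves a lone array that is assumed to vary like the other groups. The counts of genes that changed with time within a genotype stayed within 1.5 times under every setting but one, WT at 24 h without the second WT 0 h array (3681). No filter, the stricter filter, the intensity trend, the mean of all probes, the title letter as a block and cyclic loess moved no count by more than that. The quantile rescaling and the 75th percentile shift move nothing on a table already quantile normalized, and the log offset was not run since the values are log2.

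With only the 2 groups compared, those groups alone set the spread. The median SD within a group was 0.0384 in WT and 0.0425 in KO at 24 h. It was 0.0780 and 0.0431 at 0 h, 0.0658 and 0.0720 at 3 h, and 0.0421 and 0.0663 at 6 h. The fit of all arrays shares the spread over groups, so it can be too strict at 24 h and too lenient at 0, 3 and 6 h. With the 2 groups alone, KO against WT gave 8 genes at 0 h, 351 at 3 h, 0 at 6 h and 3047 at 24 h (limma). Without the first WT 0 h array it gave 254 at 0 h and 159 at 6 h; for the latter the cause was not tested. Over all arrays left out in turn, the counts ran from 183 to 1720 at 0 h, 198 to 1139 at 3 h, 0 to 589 at 6 h and 392 to 443 at 24 h, from 282 to 2220 for the joint interaction and from 3681 to 5670 for WT at 24 h. The count of the average comparison ran from 927 to 1697.

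The replicate number as a block gave 274 genes for KO against WT at 3 h and moved no other count by over 1.5 times. Same-numbered arrays of KO and WT deviated against each other at 0 h (r = -0.195), 6 h (-0.108) and 24 h (-0.137) and in both directions at 3 h (-0.0524 to 0.0507). Between times of a genotype the values ran from -0.0732 (WT 6 h against 0 h) to 0.278 (KO 3 h against 0 h). By title letter the values with KO 3 h differed: -0.278 for KO 3 h against 0 h, and -0.0925 to -0.0507 for KO against WT at 3 h. No label says what a number or a letter ties together, so arrays are taken to share only that number or letter. Whether the 0.278 or the -0.278 reflects a tie stays open. On the 2 groups alone the block gave 15, 0 and 3440 genes at 0, 6 and 24 h, and crossed numbers gave 92, 140 and 3578; the cause was not tested.

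Of the 107 list calls 104 held under cyclic loess, 104 with no filter, 73 under the stricter filter (26 lost), 68 with fry and 0 with an estimated correlation. Without the first WT 0 h array 89 held, and 4 turned: the replication list had a median interaction of 0 at 3 h and -0.10 at 6 h, and the mitosis list of -0.04 and -0.03. With each array left out in turn 67 of 107 held throughout. The leading single genes kept their direction under every setting run for them; those of the average comparison were not fitted on 2 groups alone. Past the threshold no longer were Ltf and Wfdc15b in KO against WT at 6 h with the intensity trend (adjusted p = 0.0631 and 0.0559) and on the 2 groups alone (0.0536 and 0.181), and, on the 2 groups alone, Egr1 in WT at 24 h (0.111) and in KO against WT at 0 h (0.0649).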

Other observations

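Endothelial markers in KO at 24 h had a median of -0.27 (camera adjusted p = 5.61e-02), with 8 of 13 lower, and granulocyte markers -0.33 (7.61e-02), with 5 of 10 lower. Neither was called. Endothelial markers were called without the first KO 0 h array (-0.41, 2.38e-02) or the second KO 24 h array (4.95e-02). The granulocyte fall rests on the KO 0 h arrays: without the second the median was -0.08 with 2 lower, and without the first it was -0.54 and called (2.78e-05). Stromal fibroblast markers in KO at 3 h had a median of -0.37 (1.70e-01), with 7 of 12 lower.

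The array nearest to a given one was not always of its own group. The second WT 0 h array was closest to the first KO 0 h array (r = 0.992 across all probes). The first KO 3 h array was closest to the first WT 3 h array (0.992), and the first KO 6 h array to the second WT 6 h array (0.994). The spread between arrays of a group, as the median SD over genes, ran from 0.0384 in WT 24 h to 0.0780 in WT 0 h.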
